A study of Macaca fascicularis with 16 samples.

How the data were processed

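The samples were peripheral blood mononuclear cells (PBMC) of 4 cynomolgus macaques (Macaca fascicularis), LG04, LG11, LG12 and LG15, bled before NKTT320 and 30 minutes, 2 hours and 1 day after it. Per the labels' protocols, mononuclear cells were separated on a density gradient from EDTA blood and snap frozen, and total RNA was extracted from the thawed, unfractionated cells. Ribosomal RNA was removed and stranded total RNA libraries were sequenced with single reads of 75 cycles. Groups were taken from the sample titles, which name the animal and the time of each library.

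The deposited count tables hold whole-number counts per gene that are not normalized. The submitters' processing notes name FastQC, Trimmomatic, STAR, HTSeq, DESeq and edgeR and the human builds GRCh37 and hg19, with no versions; the settings of the aligner and counter and the annotation version are not given in the sources used here. Identifiers in the deposited count tables are human Entrez gene numbers, so macaque reads were counted on human gene models. A gene that differs strongly between the species can therefore be undercounted, and reads of near-identical copies (HBA1 and HBA2, GZMB and GZMH, the KLRC genes, the histone genes) are uncertain. Strand settings of the counting are not given in the sources used here, so genes that overlap on opposite strands are uncertain as well. Several genes of the major histocompatibility region, among them TNF, LTA, HSPA1A, HSPA1B, TAP1, PSMB9, AIF1 and BAG6, are listed at 0 in all 16 libraries, which is a limit of the counting and not a measure of expression. The deposited FPKM tables hold values scaled to gene length and library size, made by the authors with a program not given in the sources used here.

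Counts were read from the tables made per animal and time. The 24369 entries of a count table were joined to 23602 gene symbols by summing entries of the same symbol (766 symbols had more than 1 entry, and 653 of these had no count in any library). Series-wide tables were compared with the tables per animal: 23 of 24 count columns and 15 of 16 FPKM columns held the same values as the library they are named for, and the exception in each was the 2 hour column of LG04, which held the values of the 1 day library of LG04. The series-wide FPKM table of 1 day ends in the middle of a line and was not used. No column of per-sample values was left without a sample. The smallest chi-square per gene over the 120 pairs of libraries was 5.53, so no library differed from another by as little as sampling noise. The counts ranged from 1417467 to 8582852 per library; a count of 3 corresponded to 0.35 to 2.12 CPM, counts scaled to library size. RNA reads without molecular identifiers are not independent molecules, so this floor covers counting error only.

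Choices made before the data were examined were the groups, the tests, the gene lists, the rule for named genes and the alternatives other than those named as added. Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and the filterByExpr filter, in 1 fit of all 16 libraries with time and animal as terms (9 residual degrees of freedom). After filtering 11545 genes were tested, and p-values were adjusted over them by the method of Benjamini and Hochberg with a threshold of 0.05. Log2 fold changes are given with a standard error (SE) derived from the reported p-value. The 5 comparisons were 3 with the pre-treatment samples and 2 between successive times; they share libraries, so their gene calls were not compared by overlap. Levels are given as mean CPM with the standard deviation (SD) over the 4 animals.

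The animal block rests on the design, since the same 4 animals were bled at each time. Deviations of libraries from their time means were correlated within an animal (median 0.56, with 23 of 24 pairs over 0.1). The lowest, 0.06, was that of LG04 between pre-treatment and 1 day. Between animals the median was -0.19, but subtracting the time means by itself pushes these correlations below 0. Of 16 libraries 13 correlated best with their own animal. LG04 at 1 day had a chi-square per gene of 12.64 against LG15 at 1 day. Against its own libraries it was 96.69 (pre-treatment), 139.6 (30 minutes) and 176.5 (2 hours), though this measure also grows with depth. It was 37.6 against LG15 at 2 hours, 56.44 against LG12 at 1 day and 86.15 against LG12 at 30 minutes. These libraries are shallower than LG15 at 1 day, so depth alone does not account for the value of 12.64. Whether the 1 day library of LG04 was misplaced was not tested. The fit was tested on simulated data with the real means and library sizes (11545 genes). Against pre-treatment, in the order 30 minutes, 2 hours and 1 day, it recovered 49, 47 and 51 of 100 genes changed by log2 1. Of 100 changed by log2 2 it recovered 93, 88 and 88, with 6, 3 and 6 false calls. Only genes with a mean log2 CPM above 2 were changed, and all genes were drawn independently. Recovery of genes with few counts, or of genes that vary together, was therefore not tested.

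For 29 gene lists with 483 members, limma's camera (limma 3.58.1) asked whether the members moved relative to the other genes, with a preset correlation between genes of 0.01 and adjustment over the 29 lists of a comparison. Calls were repeated with a correlation estimated per list and with fry, whose p-value asks whether the members of a list move, on balance, in a single direction, without setting them against other genes. The lists cover immediate-early genes, T-cell activation molecules, lymphocyte cytokines and chemokines, NF-kB and myeloid inflammatory genes, type I interferon-stimulated genes, interferon-gamma response genes, cytotoxic granule genes and iNKT-associated genes. Cell type lists cover NK cells, T cells, B cells, plasma cells, monocytes, dendritic cells, neutrophils, platelets, red cells, and eosinophils with basophils and mast cells. The others hold proliferation, glucocorticoid-induced, circadian clock, heat-shock and handling-stress, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosomal protein, histone, lymphocyte homing and apoptosis genes. A list score is the mean log2 CPM of the tested members in a library.

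Named genes were, per comparison with pre-treatment, the 8 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 1 and the same direction in 4 animals, up to 4 members past the threshold per list, and a fixed panel; small RNA genes and unnamed loci were left out. For the comparisons of successive times the numbers were 4 and 2. Other genes that are named, mostly list members past the threshold adjusted over the list alone, were chosen after their values were seen. A few genes that met these rules are not reported here. Of the panel, IL4, IL13, IL2, TNF, IL6 and CCL2 had 0, 5, 1, 0, 33 and 17 counts over the 16 libraries and did not pass the filter.

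Alternatives were size factors of DESeq2, no filter on low counts, the DESeq2 1.42.0 Wald test, no animal block, each animal left out in turn, only the 8 libraries of a comparison, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM values for genes with a mean FPKM of at least 1. Chosen after seeing the data were leaving out the 4 shallowest libraries (at most 1960744 counts), leaving out globin genes, the red-cell, monocyte or platelet score as a covariate, and the series-wide 2 hour table. Tables were handled and plots drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.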

Results

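Gene expression was measured by total RNA sequencing in blood mononuclear cells of 4 Mauritian-origin cynomolgus macaques given NKTT320, a monoclonal antibody that binds the invariant T-cell receptor of invariant natural killer T (iNKT) cells, rare lymphocytes that recognise lipids presented by CD1d. The study asked how the antibody activates iNKT cells in the living animal. Each animal was sampled before dosing and after 30 minutes, 2 hours and 1 day, which gave 16 libraries, 4 per time. Untreated animals were not analysed here, so each comparison sets times of the same animals side by side, and the drug, the passage of time and repeated bleeding share the same samples.

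Total counts ranged from 1417467 to 8582852 per library. The 4 shallowest libraries were LG12 at 1 day (1417467 counts), LG04 at 1 day (1846011), LG15 at 2 hours (1890190) and LG12 at 30 minutes (1960744). Globin genes, which mark red cells, took between 0.025% and 48.7% of the counts. They took 20.3%, 38.2%, 48.7% and 13.6% in LG04 from the pre-treatment sample to 1 day, and at most 0.172% in LG12. Animals differed more than times: the leading principal component held 42.1% of the variance, of which 89.2% lay between animals and 3.99% between times.

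**Figure D1:**
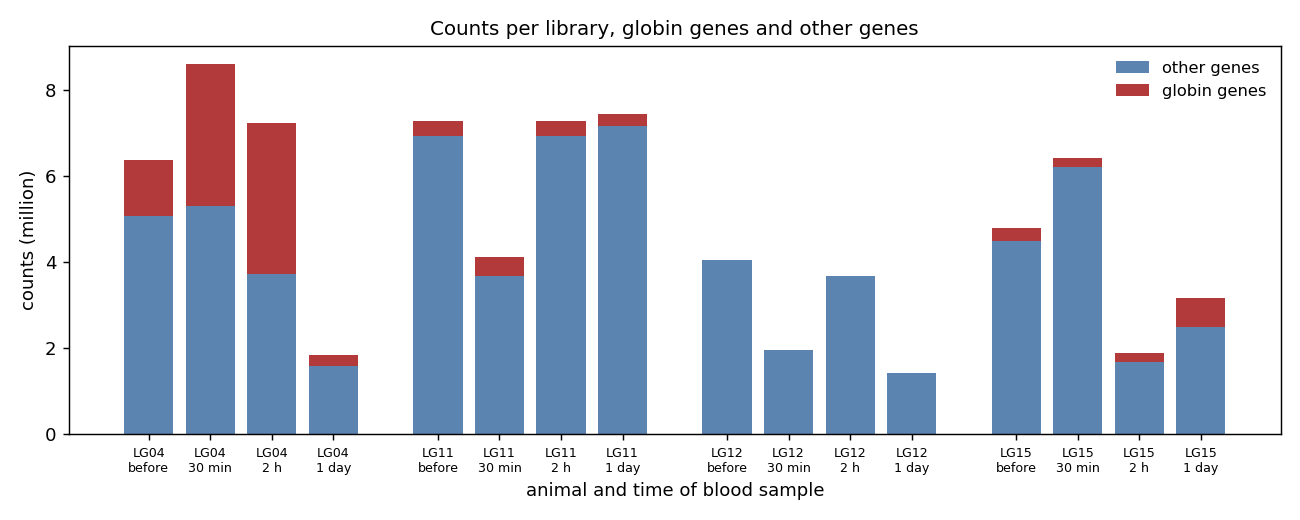
Counts per library, stacked by globin genes and all other genes, for each animal (LG04, LG11, LG12, LG15) and time of blood sample. Globin counts reach 48.7% of the library of LG04 at 2 hours, and LG12 at 1 day is the shallowest library with 1417467 counts.

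The comparison of 30 minutes with pre-treatment asked for the earliest response. Genes of the cytotoxic machinery and of NK cells were lower: the cytotoxic granule list fell by a median of 1.7-fold (log2 -0.79, 11 of 13 members lower, lower in 4 of 4 animals) and the NK-cell list by 1.4-fold (log2 -0.51, 10 of 10 members lower, 4 of 4 animals). Granulysin (GNLY), a pore-forming antimicrobial protein of cytotoxic granules, went from 81.5 ± 8.07 to 41.4 ± 7.11 CPM (SD, n = 4). Granzyme B (GZMB) went from 270.4 ± 83 to 149.6 ± 45 CPM and perforin (PRF1) from 175.3 ± 66.6 to 99.5 ± 31.5 CPM. Interferon gamma (IFNG), the main T-helper 1 and NK-cell cytokine, went from 6.46 ± 3.14 to 2.23 ± 1.36 CPM.

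In camera the adjusted p was 2.0e-19 for cytotoxic granule genes, 1.4e-14 for NK-cell markers and 4.7e-08 for lymphocyte cytokines and chemokines, and with an estimated correlation these calls held (adjusted p = 0.013, 0.013 and 0.018). Adjusted over the list alone, 8 cytotoxic genes were lower and 0 were past the threshold over all genes. They were GNLY (log2 -0.98 ± 0.20, SE), GZMH (-0.95 ± 0.22), GZMB (-0.85 ± 0.20), CST7 (-0.71 ± 0.17), PRF1 (-0.82 ± 0.25), GZMA (-1.07 ± 0.37), NKG7 (-0.76 ± 0.28) and FGFBP2 (-0.79 ± 0.32). Of the NK-cell markers 5 were lower adjusted over the list alone: SH2D1B (-0.97 ± 0.26), KLRC3 (-0.94 ± 0.28), the activating receptor NCR1 (-0.89 ± 0.26), the transcription factor EOMES (-0.51 ± 0.17) and KLRF1 (-0.51 ± 0.18). NCAM1, counted as lower, hardly changed (-0.01 ± 0.45). Lymphocyte cytokines had 5 tested members with a median of -0.67, of which IFNG (-1.41 ± 0.40) and the chemokines CCL4 (-0.98 ± 0.25) and CCL5 (-0.67 ± 0.22) passed adjusted over the list alone.

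The iNKT-associated list had a median of -0.12 (11 of 16 members lower, camera adjusted p = 0.0011), and its call was lost with adjusted p = 0.22 with an estimated correlation. Its members past the threshold adjusted over the list alone were TBX21 (-0.88 ± 0.18), which encodes the T-helper 1 transcription factor T-bet, and the interleukin 12 receptor chain IL12RB2 (-0.95 ± 0.20). ZBTB16, which encodes the iNKT transcription factor PLZF, gave 0.33 ± 0.55, CD1D 0.11 ± 0.46 and GATA3 -0.03 ± 0.22. Panel genes of activation gave CD69 -0.04 ± 0.37, EGR2 0.01 ± 0.40, NR4A1 -0.17 ± 0.27 and CXCL10 0.19 ± 1.03, and the lineage genes CD3E -0.09 ± 0.19, CD14 0.78 ± 0.59, MS4A1 0.38 ± 0.26 and NCAM1 -0.01 ± 0.45. None of these panel genes passed the threshold over all genes in edgeR; DESeq2 called TBX21 (-0.90, adjusted p = 0.029).

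Markers of B cells were higher at 30 minutes, with 14 of 14 members above their pre-treatment level and a median of 0.37 (camera adjusted p = 6.0e-06, adjusted p = 0.32 with an estimated correlation). Other cell type lists past the threshold were neutrophils (0.72, adjusted p = 0.46 with an estimated correlation), red cells (0.80, 0.68), platelets (0.38, 0.68) and plasma cells (0.40, 0.31). T-cell markers had a median of 0.06 (camera adjusted p = 0.93) and monocyte markers one of 0.34 (0.21). Immediate-early genes (median -0.21, adjusted p = 0.24 with an estimated correlation), heat-shock genes (-0.15, 0.074), circadian clock genes (-0.15, 0.14) and histone genes (-0.22, 0.59) were called lower. Glucocorticoid-induced genes (0.32, 0.32), NF-kB and myeloid inflammatory genes (0.12, 0.18) and ribosomal protein genes (0.13, 0.68) were called higher. Scores of red-cell, glucocorticoid-induced and ribosomal protein genes were higher in 2 of 4 animals and lower in 2; those of the platelet, immediate-early, heat-shock, circadian clock, histone and iNKT-associated lists went against the call in 1 of 4.

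In all, 16 of 29 lists passed camera at 30 minutes, 8 higher and 8 lower, and 3 held with an estimated correlation. No single gene was called by edgeR (0 of 11545), with 292 genes at an unadjusted p under 0.05 where chance gives 577, and a smallest adjusted p of 0.52. DESeq2 called 9 genes, all lower and 8 of them among the genes tested by edgeR, including GNLY, TBX21, CST7 and the chaperone gene HSPH1.

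**Figure D2:**
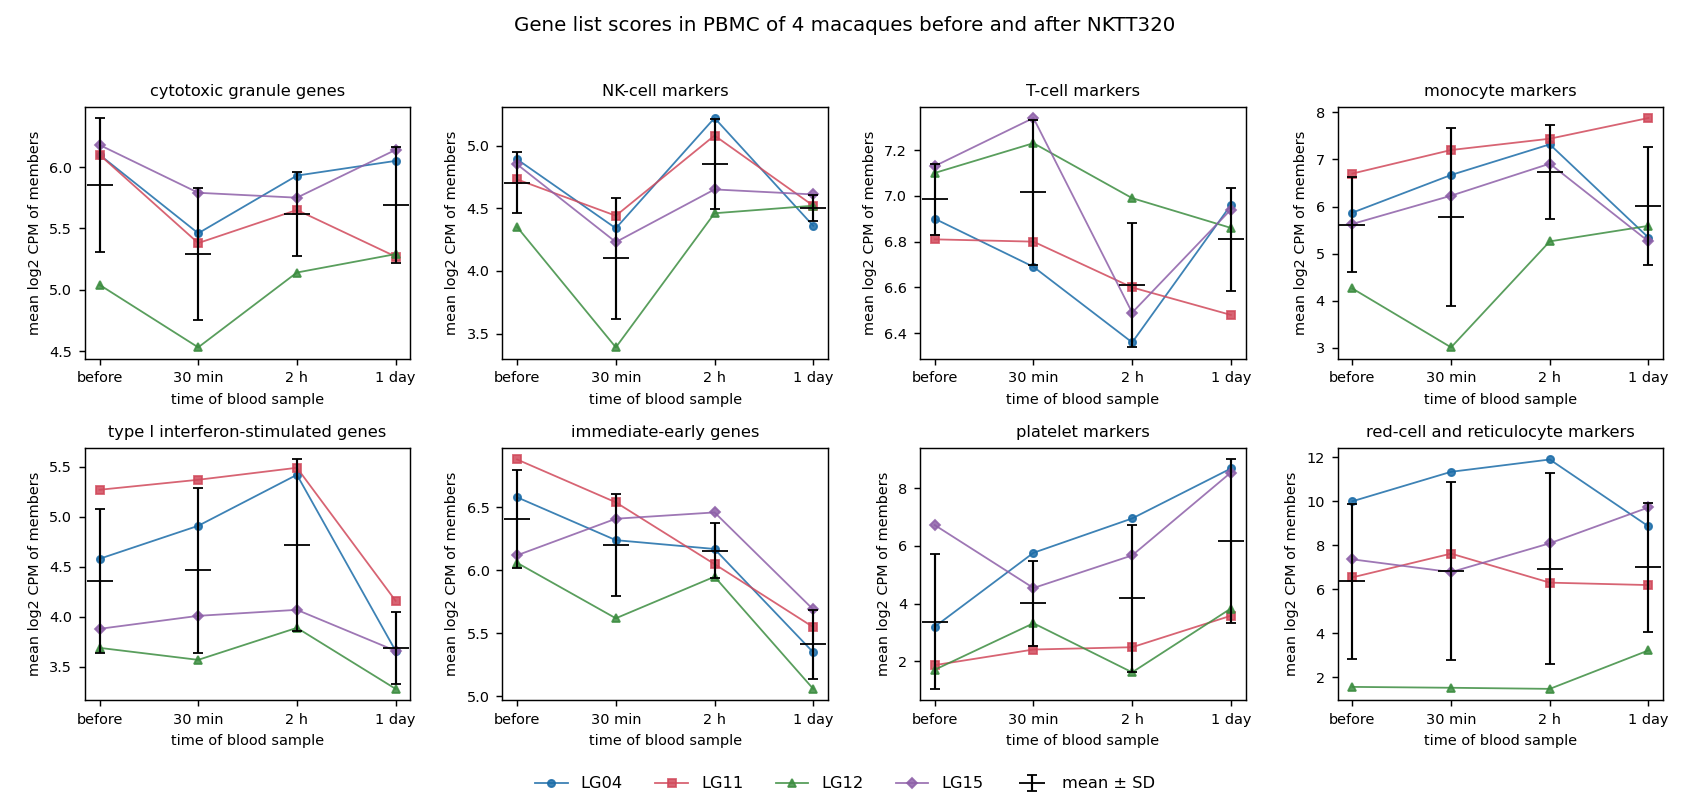
Mean log2 CPM of the tested members of 8 gene lists in each library against the time of the blood sample, with a line per animal and the mean ± SD over 4 animals in black. Cytotoxic granule and NK-cell scores are lower at 30 minutes than before in 4 of 4 animals, and immediate-early scores are lower at 1 day in 4 of 4 animals.

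At 2 hours against pre-treatment, camera with the preset correlation called monocyte markers and type I interferon-stimulated genes higher and T-cell markers lower. Each call was lost with adjusted p = 0.27 with an estimated correlation, under which 0 of 29 lists passed. The monocyte list had a median 2.0-fold higher (log2 1.00, 16 of 17 members higher, 4 of 4 animals), and CD163, a scavenger receptor of monocytes and macrophages, went from 65.2 ± 27.8 to 588.9 ± 290.6 CPM (SD, n = 4). T-cell markers had a median of -0.38 (18 of 19 members lower, 4 of 4 animals). Type I interferon-stimulated genes had a median of 0.37 (21 of 24 members higher, 4 of 4 animals).

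In camera the adjusted p was 4.4e-10 for monocyte markers, 4.2e-10 for T-cell markers and 6.3e-05 for type I interferon-stimulated genes (adjusted p = 0.27 with an estimated correlation for each). Adjusted over the list alone, 7 monocyte genes were higher, against 0 over all genes, among them CD163 (3.08 ± 0.61), VCAN (2.53 ± 0.66), FCN1 (2.03 ± 0.58), CD36 (1.99 ± 0.71), the lipopolysaccharide co-receptor CD14 (1.84 ± 0.61) and TLR2 (1.19 ± 0.42). For T cells 6 genes were lower adjusted over the list alone: CD6 (-0.77 ± 0.19), CD5 (-0.76 ± 0.17), CD8A (-0.63 ± 0.18), CD3G (-0.62 ± 0.17), TCF7 (-0.48 ± 0.17) and the T-cell receptor kinase LCK (-0.47 ± 0.16). The interferon-stimulated genes past the threshold adjusted over the list alone were IFI44 (0.87 ± 0.18) and MX1 (0.76 ± 0.21). Of other lists, PTGS2, the inducible cyclooxygenase (2.17 ± 0.37), the monocyte chemokine receptor CCR2 (1.33 ± 0.30), the lymphocyte egress receptor S1PR1 (-0.81 ± 0.15), NR4A2 (-0.98 ± 0.17), HSPH1 (-1.14 ± 0.18) and the glucocorticoid-induced co-chaperone FKBP5 (1.58 ± 0.38) passed adjusted over the list alone. NF-kB and myeloid inflammatory genes as a list had a median of 0.28 (camera adjusted p = 0.11).

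Further lists were called at 2 hours and lost with an estimated correlation. B-cell markers (median -0.41, adjusted p = 0.35 with an estimated correlation), cytotoxic granule genes (-0.30, 0.35), lymphocyte cytokines (-0.49, 0.27), iNKT-associated genes (-0.12, 0.35), immediate-early genes (-0.19, 0.27), circadian clock genes (-0.33, 0.27), heat-shock genes (-0.25, 0.27), histone genes (-0.28, 0.50) and lymphocyte homing receptors (-0.17, 0.27) were called lower. Platelet (0.66, 0.57), red-cell (0.91, 0.67) and neutrophil markers (0.37, 0.57), glucocorticoid-induced genes (0.48, 0.27), glycolysis genes (0.28, 0.35) and apoptosis genes (0.07, 0.27) were called higher. NK-cell markers had a median of 0.07 (camera adjusted p = 0.45). Mean changes were above 0 in 2 of 4 animals and below it in 2 for platelet, red-cell, neutrophil, B-cell, histone and iNKT-associated genes; platelet markers changed by 3.76 in LG04 and -1.04 in LG15, and neutrophil markers by -1.28 and 1.72. In 1 of 4 animals each, cytotoxic granule, lymphocyte cytokine, immediate-early, heat-shock, homing, glucocorticoid-induced, glycolysis and apoptosis genes went against the call.

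Of the panel, ZBTB16 gave 1.16 ± 0.54 at 2 hours, CD1D 0.75 ± 0.46, TBX21 -0.79 ± 0.18, GATA3 -0.46 ± 0.23 and IFNG -1.51 ± 0.41. ZBTB16 is also in the glucocorticoid-induced list. In unfractionated cells these values cannot be assigned to iNKT cells. The other panel genes gave CD69 -0.81 ± 0.38, EGR2 0.38 ± 0.41, NR4A1 -0.08 ± 0.27, CXCL10 0.58 ± 0.31, CD3E -0.40 ± 0.19, MS4A1 -0.42 ± 0.27 and NCAM1 1.33 ± 0.44. None passed the threshold over all genes in edgeR; TBX21 and IFNG passed adjusted over the list alone, and DESeq2 called TBX21 (-0.80, adjusted p = 0.022).

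Of the 29 lists 18 passed camera at 2 hours, 8 higher and 10 lower, and 0 held with an estimated correlation or in fry. Without LG15 9 lists passed. No single gene was called by edgeR (0 of 11545, with 858 at an unadjusted p under 0.05 and a smallest adjusted p of 0.08, for CREB5), while DESeq2 called 77 genes, 56 higher and 21 lower.

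At 1 day, immediate-early genes, which encode transcription factors and feedback regulators induced within minutes of cell stimulation, were lower than before dosing. The list fell by a median of 1.8-fold (log2 -0.87, 18 of 19 members lower, 4 of 4 animals). NR4A2, a nuclear receptor induced by antigen receptor signalling, went from 166.1 ± 25.9 to 35.2 ± 3.91 CPM (SD, n = 4), FOS from 917.3 ± 170.6 to 308.6 ± 188.3 CPM, and TNFAIP3, which encodes the NF-kB inhibitor A20, from 490.3 ± 76.9 to 155.9 ± 32.2 CPM. Platelet markers had a median 6.2-fold higher (log2 2.63, 11 of 11 members higher, 4 of 4 animals). The camera adjusted p with an estimated correlation was 0.11, and 0 members passed the threshold over all genes. The platelet score rose most in LG04, from 3.20 to 8.68. It went from 1.87 to 3.58 in LG11, 1.71 to 3.83 in LG12 and 6.72 to 8.54 in LG15. The 1 day library of LG04 lay nearer to that of LG15 (chi-square per gene 12.64) than to LG04 before dosing (96.69). Whether it was misplaced was not tested, so counts over 4 animals at 1 day may not rest on 4 independent samples.

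At this time edgeR called 26 genes, 6 higher and 20 lower, each in the same direction in 4 of 4 animals, with 1570 genes at an unadjusted p under 0.05. Among the lower genes were NR4A3 (-2.42 ± 0.35, adjusted p = 0.015), NR4A2 (-2.24 ± 0.18, adjusted p = 2.2e-04), the kinase PLK2 (-1.81 ± 0.27), the salt-inducible kinase SIK1 (-1.72 ± 0.25), FOS (-1.70 ± 0.24), TNFAIP3 (-1.66 ± 0.20, adjusted p = 0.0097), and RGS1, a regulator of G-protein signalling (-1.61 ± 0.23). The phosphatase gene DUSP1 (-1.20 ± 0.22) and NFKBIA (-0.97 ± 0.15), which encodes the NF-kB inhibitor IkB alpha, fell as well. The rule for named genes took 3 of the higher genes, TFEC (1.55 ± 0.27), PLEKHO1 (1.26 ± 0.23) and IKBIP (1.05 ± 0.17); the other higher genes were the small nucleolar RNA genes SNORA21, SNORA68 and SNORA54, named after their values were seen. DESeq2 called 387 genes, 278 higher and 109 lower, which included all 26.

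Camera gave immediate-early genes an adjusted p of 2.2e-22, and the call held (adjusted p = 0.015 with an estimated correlation). Adjusted over the list alone 13 members were lower and 1 higher, against 4 lower over all genes (NR4A2, FOS, NR4A3 and DUSP1). The lower members included JUN (-2.0 ± 0.39), FOSB (-1.65 ± 0.33), JUNB (-1.53 ± 0.58), DUSP2 (-1.30 ± 0.30) and ZFP36 (-0.95 ± 0.26), and the higher one was MYC (0.83 ± 0.24). Type I interferon-stimulated genes had a median of -0.67 (22 of 24 members lower, 10 adjusted over the list alone, 4 of 4 animals; camera adjusted p = 7.5e-11), with adjusted p = 0.11 with an estimated correlation. Examples were IFI27 (-2.30 ± 0.58), IFI6 (-1.68 ± 0.42) and IFI44L (-1.66 ± 0.37). NF-kB and myeloid inflammatory genes had a median of -0.25 (camera adjusted p = 0.018, adjusted p = 0.11 with an estimated correlation), and CXCL3 in that list gave 2.26 ± 0.73.

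Platelet genes were called higher by camera (adjusted p = 1.3e-14, adjusted p = 0.11 with an estimated correlation), and 11 of 11 members passed adjusted over the list alone. The platelet chemokines PPBP (3.15 ± 0.86) and PF4 (3.01 ± 0.76) and the collagen receptor GP6 (3.08 ± 0.66) were among the largest. Red-cell markers (median 1.22, adjusted p = 0.67 with an estimated correlation) and histone genes (0.45, 0.61) were called higher too. Called lower were interferon-gamma response genes (-0.39, 0.33), T-cell markers (-0.18, 0.61), neutrophil markers (-1.34, 0.61), circadian clock genes (-0.21, 0.11) and ribosomal protein genes (-0.17, 0.61). Of the interferon-gamma response genes, IRF1 (-0.58 ± 0.11) and GBP2 (-0.68 ± 0.15) were lower adjusted over the list alone, and ANKRD22 (2.42 ± 0.60) and CD274, which encodes the checkpoint ligand PD-L1 (1.40 ± 0.46), were higher. The red-cell score was higher in 2 of 4 animals and lower in 2, and the NF-kB, T-cell, neutrophil and histone scores went against the call in 1 of 4. With the platelet score as a covariate, chosen after seeing the data, the neutrophil median was 0.12.

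Cytotoxic granule genes at 1 day had a median of -0.29 (camera adjusted p = 0.071), NK-cell markers -0.20 (0.19), monocyte markers 0.29 (0.071), B-cell markers 0.01 (0.93) and iNKT-associated genes -0.02 (0.82). The panel gave ZBTB16 0.04 ± 0.58, CD1D 0.57 ± 0.47, TBX21 -0.14 ± 0.18, GATA3 0.09 ± 0.23, IFNG -0.97 ± 0.42, CD69 -0.91 ± 0.38, EGR2 -0.36 ± 0.44, NR4A1 -0.83 ± 0.28, CXCL10 -0.18 ± 0.34, CD3E -0.19 ± 0.19, CD14 1.83 ± 0.62, MS4A1 -0.04 ± 0.27 and NCAM1 0.34 ± 0.46. None of these passed over all genes in edgeR; DESeq2 called CD14 (2.05, adjusted p = 0.032).

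The count of 26 genes depended on the libraries and the model. It was 1, 2, 1 and 67 without LG04, LG11, LG12 and LG15, 0 without the 4 shallowest libraries, and 3 with no replicate block. With no filter it was 70, with the platelet score as a covariate 1, and with the monocyte score 177. The direction varied as well. Of the 67 without LG15, 47 were higher and 15 were among the 26. With no filter 34 of 70 were higher, and with the monocyte score 110 of 177. The genes called without LG04, LG11 or LG12, with no replicate block or with the platelet score were all lower. NR4A2 passed without each animal in turn but not without the shallow libraries (log2 -2.39, adjusted p = 0.067). The number of lists past the threshold, 11 (3 higher, 8 lower), was 7 without LG12 and 5 without LG15.

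**Figure D3:**
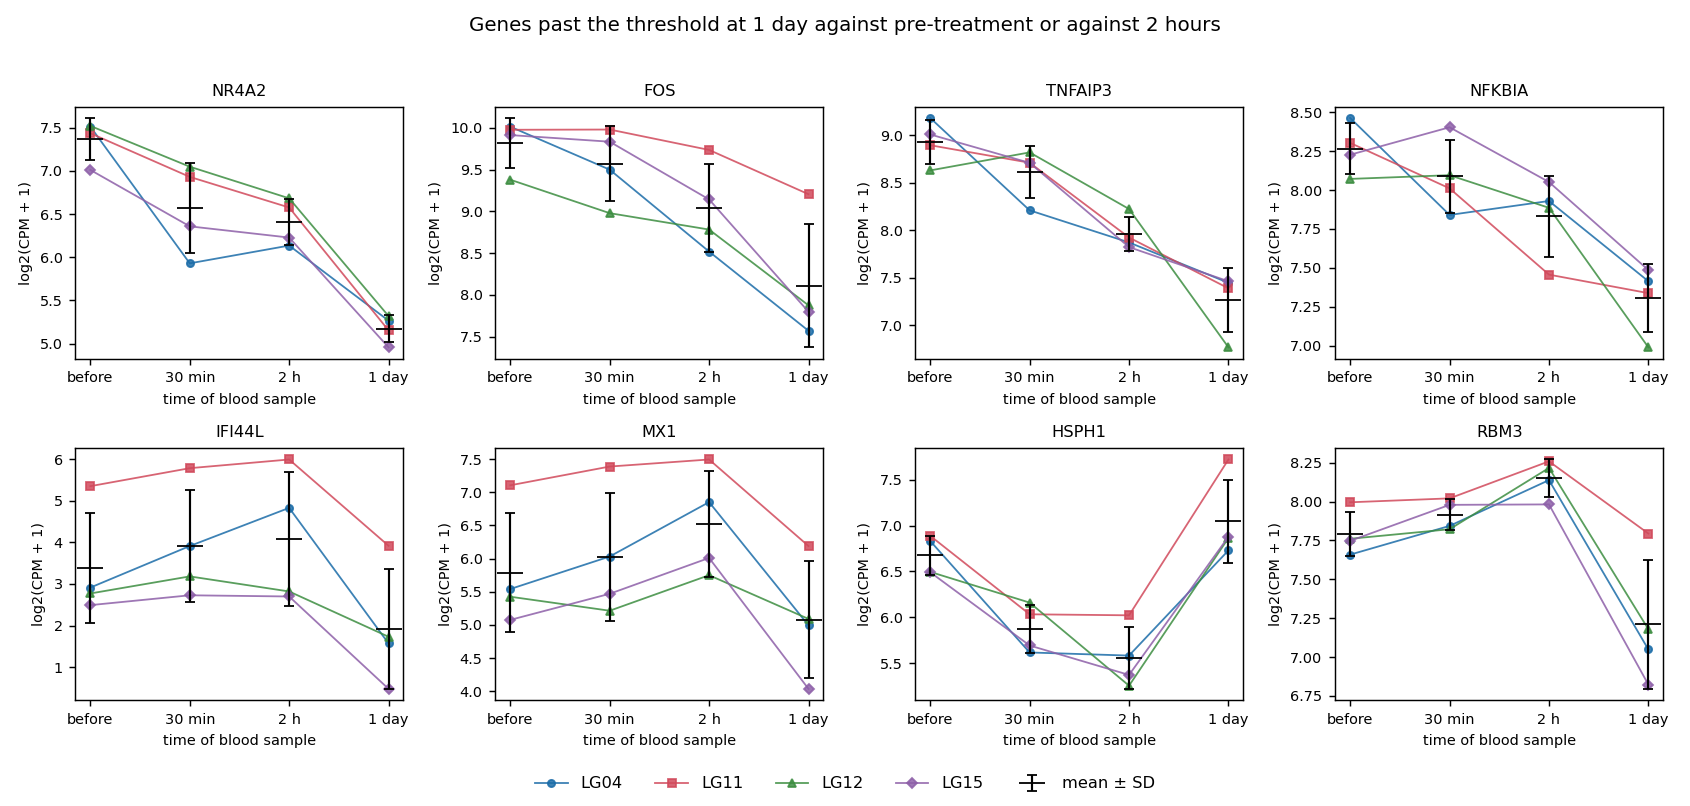
Expression of 8 genes past the threshold at 1 day against pre-treatment or against 2 hours, as log2(CPM + 1) against the time of the blood sample, with a line per animal and the mean ± SD over 4 animals in black. NR4A2, FOS, TNFAIP3 and NFKBIA are lower at 1 day than before in 4 of 4 animals, and HSPH1 is higher at 1 day than at 2 hours in 4 of 4 animals.

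Between 30 minutes and 2 hours the NK-cell markers rose by a median of 1.6-fold (log2 0.71, 10 of 10 members higher, 4 of 4 animals; camera adjusted p = 2.1e-13, adjusted p = 0.027 with an estimated correlation). The rise and the earlier fall share the 30 minute libraries, so low values in those libraries alone would give both. Adjusted over the list alone 8 of the NK-cell markers rose, against 0 over all genes, among them NCR1 (1.03 ± 0.27), KLRC3 (0.99 ± 0.28) and KLRD1 (0.69 ± 0.19). NCAM1 (1.34 ± 0.45) was also among them, but it had not fallen at 30 minutes (-0.01 ± 0.45) and rose above its pre-treatment level (1.33 ± 0.44). Cytotoxic granule genes had a median of 0.39 (10 of 13 members higher, adjusted p = 0.20 with an estimated correlation), with GZMB at 0.75 ± 0.20 and GNLY at 0.71 ± 0.20. B-cell markers (median -0.73, 14 of 14 members lower, adjusted p = 0.16 with an estimated correlation), T-cell markers (-0.42, 0.16), plasma-cell markers (-0.58, 0.24) and lymphocyte homing receptors (-0.36, 0.16) were called lower. Monocyte markers (0.70, 17 of 17 members higher, adjusted p = 0.24 with an estimated correlation), type I interferon-stimulated genes (0.26, 0.34), glycolysis genes (0.23, 0.51) and the 3 tested eosinophil, basophil and mast-cell markers (0.90, 0.16) were called higher. Of the 29 lists 10 passed, 6 higher and 4 lower, and 0 of 11545 genes were called by edgeR, with 531 at an unadjusted p under 0.05, against 14 by DESeq2, of which 8 were genes of near 0 counts outside the edgeR filter. In 1 of 4 animals each, the score went against the call for cytotoxic granule, B-cell, plasma-cell and glycolysis genes.

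Between 2 hours and 1 day the type I interferon-stimulated genes fell by a median of 2.1-fold (log2 -1.07, 24 of 24 members lower, 4 of 4 animals; camera adjusted p = 2.2e-24, adjusted p = 0.028 with an estimated correlation). Adjusted over the list alone 15 of them were lower, and 4 over all genes: IFI44L (-2.50 ± 0.37), IFI44 (-1.66 ± 0.20), the antiviral GTPase MX1 (-1.47 ± 0.22) and XAF1 (-1.19 ± 0.17). IRF9, a subunit of the transcription factor ISGF3 that drives these genes, fell by 1.29 on the log2 scale (SE 0.16). Immediate-early genes (median -0.74, 18 of 19 members lower) and NF-kB and myeloid inflammatory genes (-0.61, 10 of 12 members lower) fell too, each with adjusted p = 0.028 with an estimated correlation, and NR4A2 gave -1.26 ± 0.18 and PTGS2 -1.74 ± 0.39. The chaperone gene HSPH1 (1.52 ± 0.18), the co-chaperone FKBP4 (1.61 ± 0.22) and the peptide transporter SLC15A2 (1.71 ± 0.22) rose.

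In all edgeR called 12 genes between 2 hours and 1 day, 4 higher and 8 lower, with 1455 at an unadjusted p under 0.05; DESeq2 called 118, which included all 12. Outside the rule, and named after their values were seen, were NFIL3 (-1.23 ± 0.18), the cold-inducible RNA-binding protein RBM3 (-0.93 ± 0.14) and SNORA68. Without LG04, LG11, LG12 and LG15 the count was 2, 1, 0 and 0, and it was 0 without the 4 shallowest libraries and with no replicate block. With only the 8 libraries compared it was 15, 13 of them higher, and 1 was among the 12.

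Platelet markers had a median of 1.90 in that comparison (11 of 11 members higher, 10 adjusted over the list alone; adjusted p = 0.20 with an estimated correlation), and histone (0.67, 0.20), B-cell (0.37, 0.46) and T-cell markers (0.21, 0.49) were called higher. Called lower were neutrophil (-1.56, adjusted p = 0.32 with an estimated correlation), monocyte (-0.54, 0.49) and NK-cell markers (-0.31, 0.44), interferon-gamma response (-0.65, 0.20), glucocorticoid-induced (-0.39, 0.20), glycolysis (-0.21, 0.46), ribosomal protein (-0.27, 0.46) and apoptosis genes (-0.18, 0.069). The heat-shock list was called higher by camera (adjusted p = 0.0088, adjusted p = 0.20 with an estimated correlation) with a mean of 0.12 and a median of -0.08; HSP90AA1 (0.79 ± 0.15) and HSPD1 (0.61 ± 0.14) were above 0 and DDIT3 (-1.31 ± 0.35) below it. Of the 29 lists 16 passed, 5 higher and 11 lower. Monocyte, T-cell, glycolysis and heat-shock scores were higher in 2 of 4 animals and lower in 2, and NK-cell, neutrophil and ribosomal protein scores went against the call in 1 of 4.

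T-cell activation molecules, dendritic-cell markers, proliferation, oxidative phosphorylation and cholesterol synthesis genes were not called in any comparison. At 2 hours against pre-treatment their medians were -0.19, 0.50, 0.14, 0.13 and 0.03, with camera adjusted p of 0.15, 0.10, 0.49, 0.11 and 0.84. Over the 145 pairs of list and comparison, the median or the mean went against the direction of camera in 12, of which 1 was past the threshold, the heat-shock list between 2 hours and 1 day.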

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

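The tests of the 3 patterns were chosen after the results were seen, except the test of platelet RNA; that test and the splits of the libraries were set out before their results were seen, though the 7 list medians followed through the splits were picked from the results.

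NK-cell and cytotoxic granule genes were lower at 30 minutes. With the red-cell score in the model the medians were -0.80 for cytotoxic granule genes and -0.59 for NK-cell markers, and without the 4 shallowest libraries they were -0.76 and -0.67, which argues against red-cell RNA and shallow libraries as the whole cause. A lower share of lymphocytes of every kind would lower T-cell markers as much, but the cytotoxic score changed by -0.60 relative to the T-cell score (SD 0.12, lower in 4 of 4 animals) and the NK-cell score by -0.64 (SD 0.39, 4 of 4 animals). Fewer NK cells and cytotoxic T cells in the blood, or less RNA of these genes per cell, may each underlie the pattern and were not tested apart. The drug, repeated bleeding and time since the first sample share the same libraries, so none of them could be singled out.

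Monocyte markers were higher and T-cell markers lower at 2 hours in camera with the preset correlation; both calls were lost with an estimated correlation (adjusted p = 0.27 each), under which 0 of 29 lists passed. With the red-cell score in the model the medians were 1.02 and -0.31, and without LG04, whose 2 hour library holds the highest share of globin, they were 0.89 and -0.33, which argues against red-cell RNA and a misplaced library of LG04. A lower share of lymphocytes that raises every other cell type alike cannot be told apart from a change in monocytes: the monocyte score rose by 0.79 more than the neutrophil score (SD 1.45) and by 0.30 more than the platelet score (SD 1.96), both within the spread between 4 animals. A shift in cell shares is a candidate explanation, as is a response within monocytes. The drug, bleeding and time stay open and untested.

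Immediate-early genes were lower at 1 day. The median was -0.88 without the 4 shallowest libraries and -0.68 with the platelet score in the model. This argues against shallow libraries and platelet RNA as the whole cause of the lower list median. Without the shallow libraries the 1 day values came from LG11 and LG15 alone. Calls of single genes held less well: 26 fell to 0 without the shallow libraries and to 1 with the platelet score. NR4A2 had an adjusted p of 0.067 in edgeR without the shallow libraries. Fewer monocytes are argued against as the whole cause too: with the monocyte score in the model the median was -0.97 and the call held (camera adjusted p = 3.2e-20), and the immediate-early score changed by -1.33 in LG11 and -0.99 in LG12, where the monocyte score rose by 1.18 and 1.33. Handling of the pre-treatment samples alone is argued against as well, since the genes fell between 2 hours and 1 day, without a pre-treatment sample (median -0.74, lower in 4 of 4 animals, adjusted p = 0.028 with an estimated correlation), against medians of -0.21 at 30 minutes and -0.19 at 2 hours. Handling that differed at 1 day, time and a response to the drug stay open and untested.

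Each comparison was repeated over the 35 splits of its 8 libraries into 4 and 4. Since the animals pair the libraries, the real split compares with the 8 that part every pair of an animal, which are too few for a share under 0.05. For list medians, the real size and the highest other among these 8 were 0.79 and 0.47 for cytotoxic granule genes at 30 minutes, 0.51 and 0.38 for NK-cell markers at 30 minutes, 1.00 and 0.77 for monocyte markers at 2 hours, 0.87 and 0.82 for immediate-early genes at 1 day, 2.63 and 1.96 for platelet markers at 1 day, 0.71 and 0.54 for NK-cell markers between 30 minutes and 2 hours, and 1.07 and 0.68 for type I interferon-stimulated genes between 2 hours and 1 day. Most of all 35 splits keep both libraries of at least 1 animal together. Over these 35, with the real split counted, 1, 2, 4, 4, 3, 2 and 1 gave a median as large in that order. The highest others were 0.68, 0.53, 1.07, 1.13, 3.55, 0.76 and 1.05.

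The number of lists past the threshold was 16 at 30 minutes, 18 at 2 hours, 11 at 1 day, 10 between 30 minutes and 2 hours and 16 between 2 hours and 1 day, and the highest other among the 8 splits was 13, 15, 12, 11 and 14. Over all 35 splits, with the real one counted, 1, 2, 6, 10 and 2 gave as many. The highest others were 13, 18, 13, 15 and 16. For called genes, 26 at 1 day and 12 between 2 hours and 1 day, the highest other among the 8 was 0 in each. Over all 35 splits 2 and 2 gave as many, with the real one counted, and the highest others were 173 and 201. In the other 3 comparisons the real number of genes was 0, which 35 of 35 splits reach by construction, so the splits say nothing there; the highest others were 339 at 30 minutes, 1 at 2 hours and 0 between 30 minutes and 2 hours. The splits with 339, 173 and 201 genes put both libraries of at least 1 animal on the same side. The fit holds a term for the animal, so steady differences between animals do not account for these numbers. What they reflect was not tested.

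Some single libraries lay far from the other 3 of their time, by a gap over 0.829 of the range. Chance passes this in about 1 in 20 groups, and 19 of 264 groups passed where 13 would by chance. LG12 was low in the score of NF-kB and myeloid inflammatory genes before dosing (4.37, others 5.33 to 5.48), at 30 minutes (4.57, others 5.62 to 5.73) and at 1 day (4.64, others 5.15 to 5.17), in interferon-gamma response genes at 30 minutes (4.01, others 5.04 to 5.23) and in cytotoxic granule genes before dosing (5.04, others 6.10 to 6.18). In log2 CPM LG12 was low for FOS before dosing (9.38, others 9.91 to 10.01), ZBTB16 at 30 minutes (1.57, others 3.59 to 3.85), IRF9 at 2 hours (5.51, others 6.06 to 6.14) and TNFAIP3 at 1 day (6.76, others 7.38 to 7.46).

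LG11 was high in monocyte markers at 1 day (7.88, others 5.26 to 5.59), in cholesterol synthesis genes before dosing (5.03, others 4.37 to 4.44) and at 2 hours (5.11, others 4.31 to 4.40), in IFI44L before dosing (5.33, others 2.33 to 2.80), and in DUSP1 (9.19, others 6.84 to 7.17) and HSPH1 at 1 day (7.71, others 6.72 to 6.87). LG04 was low in circadian clock genes at 30 minutes (4.89, others 5.17 to 5.23) and high in histone genes (4.84, others 3.79 to 3.96) and EGR2 (3.89, others 3.57 to 3.62) at 2 hours. LG15 was low in NR4A2 before dosing (7.0, others 7.43 to 7.52). No explanation was tested for these libraries.

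Some values are listed because successive times were tested against each other. Between 30 minutes and 2 hours the median of NK-cell markers was 0.71. Between 2 hours and 1 day 12 genes passed the threshold (2, 1, 0 and 0 without LG04, LG11, LG12 and LG15), and the medians were -0.74 for immediate-early genes, -0.61 for NF-kB and myeloid inflammatory genes and -1.07 for type I interferon-stimulated genes.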

How the results depend on the processing

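Tests chosen after the results were seen were those without the 4 shallowest libraries, without globin genes, with the red-cell, monocyte or platelet score as a covariate, and with the series-wide 2 hour table. Of 71 list calls, 71 kept direction and call with DESeq2 size factors and 69 without globin genes. With no filter 61 did, and with no replicate block 60. Without LG04, LG11, LG12 and LG15, 52, 54 (of 70 that could be computed), 60 and 45 did. The number was 60 without the shallow libraries, 60 with the red-cell, 53 with the platelet and 50 with the monocyte score. With the series-wide 2 hour table it was 10 of 18. Of 61 gene results 59, 59, 59 and 37 did under the first 4 of these settings. Without LG04, LG11, LG12 and LG15 in turn 33, 35, 37 and 41 did. The number was 35 without the shallow libraries, 40 with FPKM under each pseudocount and 41 with the 8 libraries compared alone. It was 40 with the platelet, 54 with the red-cell and 56 with the monocyte score, and 57 with DESeq2. Panel genes not past the threshold counted as kept when they stayed so. Calls lost were 22 without the shallow libraries, which left none, and 19 with no replicate block. They were 19, 20, 21 and 13 without each animal in turn. They were 20 with the 8 libraries alone, 17 with the platelet score, 16 with FPKM and 4 with the red-cell score. With an estimated correlation 8 lists kept their call and in fry 14. Unless stated otherwise, the cause was not tested.

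Genes past the threshold, in the order 30 minutes, 2 hours and 1 day against pre-treatment, 2 hours against 30 minutes and 1 day against 2 hours, were 0, 0, 26, 0 and 12. DESeq2 called 9, 77, 387, 14 and 118. With no filter 7 were called at 2 hours and 70 at 1 day. FPKM with a pseudocount of 1 gave 1, 1 and 6 against pre-treatment and 2 for the last comparison, and with 0.1 it gave 1, 1, 7 and 2; the median of all genes shifted there by -0.10 to -0.22. With no replicate block, 3 genes were called at 1 day and 0 in the last comparison. The 8 libraries of 1 day and pre-treatment alone gave 1, with 3 residual degrees of freedom. Those of 1 day and 2 hours alone gave 15, 13 higher and 2 lower, of which 1 was among the 12 of the main fit. Without the shallow libraries 0 and 0 were called, with fewer samples. The monocyte score gave 177 at 1 day, and the platelet score 1 and 4. Leaving out an animal gave 1 to 67 at 1 day and 0 to 2 in the last comparison.

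Lists past the threshold were 16, 18, 11, 10 and 16. An estimated correlation gave 3, 0, 1, 1 and 3, and fry 3, 0, 5, 1 and 5. At 2 hours the monocyte score gave 8 and the series-wide table, which repeats the 1 day library of LG04, 11. Leaving out an animal gave 9 to 19 at 2 hours, the lowest without LG15, and 5 to 14 at 1 day, with 7 without LG12 and 5 without LG15.

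Some lists changed direction. At 30 minutes platelet markers went from 0.38 to -0.10 without the shallow libraries, and ribosomal protein genes, 0.13, ranged from 0.00 (without LG15) to 0.15 without an animal. At 2 hours platelet markers, 0.66, ranged from -0.23 (without LG04) to 1.82. Red-cell markers were -0.06 at 30 minutes and -0.03 at 2 hours with the red-cell score, and monocyte markers -0.07 at 2 hours with the monocyte score, by construction; neutrophil markers were then -0.28. The series-wide table gave red-cell markers -0.21. The platelet score took neutrophil markers at 1 day from -1.34 to 0.12. Glycolysis genes between 30 minutes and 2 hours went from 0.23 to 0.02 (lower in camera) without the shallow libraries and to -0.09 with the monocyte score, and T-cell markers between 2 hours and 1 day from 0.21 to -0.05 without the shallow libraries.

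Panel genes that changed direction were not past the threshold. At 30 minutes, EGR2 was -0.01 with DESeq2 size factors, -0.02 with no filter, with DESeq2 and without globin genes, -0.08 and -0.12 with FPKM, and -0.01 with the platelet score. CD1D was -0.01 with FPKM and a pseudocount of 1, -0.00 with the red-cell and -0.17 with the monocyte score. CXCL10 was -0.03 and -0.05 with FPKM and -0.04 with no replicate block. ZBTB16 was -0.04 and NCAM1 0.08 with no replicate block; NCAM1 was 0.36 without the shallow libraries and 0.11 with the platelet score. GATA3 was 0.04 with the monocyte score, and CD69 0.05 with that and with the red-cell score.

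At 2 hours, CD1D was -0.00 with the monocyte and NR4A1 0.17 with the platelet score. At 1 day, ZBTB16 was -0.01 with no filter, -0.15 with no replicate block, -0.04 and -0.02 with FPKM, -0.05 without the shallow libraries and -0.12 with the red-cell score. GATA3 was -0.14 and -0.16 with FPKM and -0.01 without the shallow libraries. MS4A1 was 0.13 with no replicate block, 0.06 without the shallow libraries and 0.30 with the platelet score. NCAM1 was -0.06 with FPKM and a pseudocount of 0.1 and -0.28 with the monocyte score.

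Without an animal, values at 30 minutes ranged from -0.22 to 1.09 for ZBTB16, -0.10 to 0.49 for CD1D, -0.14 to 0.06 for GATA3, -0.27 to 0.12 for CD69, -0.25 to 0.16 for EGR2, -0.12 to 0.53 for CXCL10, -0.24 to 0.01 for CD3E and -0.32 to 0.31 for NCAM1, and at 2 hours from -0.26 to 0.10 for NR4A1. At 1 day they ranged from -0.64 to 0.70 for ZBTB16, -0.27 to 0.18 for TBX21, -0.11 to 0.31 for GATA3, -0.83 to 0.32 for EGR2, -0.30 to 0.02 for CXCL10, -0.29 to 0.18 for MS4A1 and -0.15 to 0.61 for NCAM1. Depth limits genes of few counts: a count of 3 stands for 2.12 CPM in the shallowest library.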

Other observations

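The small RNA genes and single genes given here were chosen after the results were seen; the test of 10 chaperone genes was set out before its result was seen.

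Small nucleolar and spliceosomal RNA genes were not among the lists, and no test of the group was run. At 1 day against pre-treatment 3 of them passed the threshold over all genes. Of 73 tested, 69 had a log2 change above 0 and 53 were higher at an unadjusted p under 0.05 in edgeR, against 978 of all 11545 genes, with a median of 1.23, or 1.09 without the 4 shallowest libraries. At 30 minutes and 2 hours the medians were 0.38 and 0.22, and -0.00 and -0.01 without those libraries. Between 2 hours and 1 day 69 of the 73 were higher, 42 of them at an unadjusted p under 0.05 in edgeR. The median there was 1.19, or 1.10 without those libraries. Their share of the counts ranged from 0.16% to 1.09%.

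No gene passed the threshold at 2 hours against pre-treatment in edgeR (858 at an unadjusted p under 0.05, 77 called by DESeq2). The 10 genes with the smallest p were CREB5 (2.71 ± 0.39, SE), STEAP4 (3.26 ± 0.48), HSPH1 (-1.14 ± 0.18), KCNJ2 (2.49 ± 0.41), PTGS2 (2.17 ± 0.37), NR4A2 (-0.98 ± 0.17), MDM2 (0.80 ± 0.15), NRG1 (2.78 ± 0.51), S1PR1 (-0.81 ± 0.15) and PLK2 (-1.35 ± 0.25).

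The higher HSPH1 and FKBP4 and lower RBM3 at 1 day than at 2 hours led to the hypothesis of a change in the heat-shock response, since RBM3 is induced by cold and chaperones by heat. Of 10 other chaperone genes picked without looking at their values, 8 were tested. In the fit 8 of 8 were above 0, with a median of 0.48 (camera p = 8.0e-07, 0.019 with an estimated correlation), and their mean was higher in 4 of 4 animals. Adjusted over the list alone 5 passed, and 0 over all genes. DNAJB4 (0.02 ± 0.41) and DNAJB6 (0.15 ± 0.19) were higher in 2 animals and lower in 2, and the other tested members were higher in 4 of 4. CIRBP, also induced by cold and looked at after RBM3, gave -0.73 ± 0.13 (adjusted p = 0.088). Against pre-treatment, HSPH1, FKBP4 and RBM3 gave -1.14 ± 0.18, -1.01 ± 0.22 and 0.36 ± 0.14 at 2 hours. At 1 day they gave 0.38 ± 0.17, 0.60 ± 0.21 and -0.56 ± 0.14, and none passed the threshold in edgeR at either time. The heat-shock and handling-stress list was chosen before the data were examined. Between 2 hours and 1 day its median was -0.08, against the direction of its camera call. That call was lost with an estimated correlation (adjusted p = 0.20, higher in 2 of 4 animals). HSPA1A, HSPA1B and HSPB1 of that list were not tested, and it also holds other stress genes such as DDIT3. A change in some chaperone genes is in line with the test of the 10 genes but was not shared by the whole list; whether it arose in the animals or in the handling of the blood was not tested.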
